A study of Mus musculus with 5 samples.

How the data were processed

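RNA was measured by RNA sequencing in inguinal white adipose tissue (iWAT), a subcutaneous fat depot of the mouse. The series holds 5 libraries in 5 groups, 1 library per group. Floxed mice carry the target gene flanked by recombination sites and stand for the control genotype, and ATRβKO mice lack thyroid hormone receptor β (TRβ, gene Thrb) in adipocytes, per the labels. Floxed mice given vehicle, floxed mice given T3 (triiodothyronine, the active thyroid hormone) and ATRβKO mice given T3 form the first table. Floxed and ATRβKO mice on a high-fat diet (HFD) form the second. Per the labels' protocols, injections were given daily for 7 days and tissue was taken 24 hours after the last, each vehicle or T3 library was made from the pooled tissue of 3 mice, and the diet lasted 2 to 3 months. The labels do not say whether the HFD libraries were pooled.

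Libraries were made with an Illumina TruSeq protocol and sequenced on a NovaSeq instrument with paired reads, per the labels' protocols. The submitters' processing notes name HISAT2, StringTie and the mouse build GRCm39, without versions or settings. The deposited values were taken as FPKM (fragments scaled to transcript length and to the number of mapped fragments). No header or label names that unit. It was inferred from non-integer values whose sums differ between libraries and from the naming of StringTie. FPKM divides by transcript length and by library total, so genes that take a large share of a library lower the values of all others. The notes do not say whether reads were counted by strand, so overlapping genes on opposite strands and near-identical copies can share or split reads. The tables hold 53700 and 55416 genes, of which 53271 are in both. As the tables could have been normalized separately, log2 ratios were made only within a table, and levels set side by side across tables are descriptive.

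No counts were used, so depth is not stated. It was estimated from the value of 1 fragment in single-exon genes, which gave 11.6 M fragments for floxed vehicle, 12.0 for floxed T3, 12.3 for the library labelled ATRβKO (T3), 18.9 for floxed HFD and 12.0 for the library labelled ATRβKO (HFD). The last rests on 98 genes and the others on at least 406. The search covered a limited range of depths, so a very low depth could not have been returned. At these depths a gene with 1 kb of transcript at 1 FPKM stands for about 12 to 19 fragments, so values near 1 FPKM carry a large counting error. A value of 0 can be a failed estimate, so such genes are described as listed at 0 and no fold is given against them.

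With 1 library per group there is no spread between animals, no statistical test and no p-value. A gene was called higher or lower by size alone, where the log2 ratio of FPKM plus a pseudocount of 1 was at least 1 in absolute value and the higher library reached 1 FPKM. Folds in the text are plain ratios of FPKM, and log2 ratios include the pseudocount, which makes the difference of low genes look smaller. For 37 gene lists with 729 entries, the median log2 ratio of the members at 1 FPKM or more in the higher library was set against 10000 random lists of equal size, drawn from 20 bins of mean expression. A list is said to stand apart where its median lies outside the central 95% of the random medians, and it needed 5 measured members. This describes the libraries, since genes are not replicates. One list, of sex-linked transcripts, had too few members and was not evaluated.

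The size rule, the lists and the rule for naming genes were fixed before the data were examined. The rule names Thrb and Thra, the 6 genes with the largest and the 6 with the smallest log2 ratio at 5 FPKM or more (leaving out predicted genes, receptor segments, ribosomal proteins and pseudogenes), up to 4 members of each list that stands apart, and 10 genes of adipose metabolism. Because many lists stood apart it took 110, 116 and 98 genes in the 3 comparisons, and the text gives examples from them. Genes named outside the rule are said to have been chosen after their values were seen.

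The fraction of a T3 difference kept in the library labelled ATRβKO (T3) was the log2 ratio of that library to vehicle divided by the log2 ratio of floxed T3 to vehicle. Since these ratios share the vehicle library, it was also computed with the roles of the 3 libraries exchanged. For the correlation of the T3 and genotype log2 ratios, which share the floxed T3 library, 100 simulated sets of unchanged libraries gave the value with no effect. Their scatter was that between vehicle and the library labelled ATRβKO (T3). Alternatives were a pseudocount of 0.1 or 5 FPKM, a floor of 5 FPKM or none, rescaling to a median log2 ratio of 0, rescaling by trimmed means of M values (TMM, own implementation without weights), leaving out the 50 most abundant genes, size rules of 1.5-fold and 4-fold, random lists without matching and list means.

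Gene structure came from GENCODE M21, which is on another build than the files, so no coordinates are printed and only lengths, introns, base composition and overlaps by Ensembl identifier were used. It holds 97.1% of the identifiers of the first table and 94.1% of those of the second. The procedure was tested on a simulated pair of libraries with 14528 genes made from the floxed vehicle values and the scatter between vehicle and the library labelled ATRβKO (T3). Of 50 genes changed at each size, the size rule recovered 0 at 1.5-fold, 17 at 2-fold, 50 at 4-fold and 50 at 8-fold, and it called 1.29% of unchanged genes. That rate leaves out genes under 1 FPKM in vehicle. The pair that supplied the scatter, which is not known to be unchanged, itself had 277 genes higher and 272 lower of 15175. The simulated rate can therefore be too low. Of 200 random lists of 20 genes, 6.5% stood apart with no shift. Their genes scattered independently, so a low share was built in. It does not tell how often lists of genes that vary together stand apart. Between vehicle and the library labelled ATRβKO (T3), 8 lists stood apart upward and 9 downward. Computing used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.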

Results

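Expression was profiled in iWAT of floxed mice given vehicle or T3, ATRβKO mice given T3, and floxed and ATRβKO mice on HFD, with 1 library per group. The series title names the adipocyte receptor and the use of glucose as the subject. There are no replicates, so no difference below could be set against a spread between animals. The summed FPKM was 752569 for floxed vehicle, 787969 for floxed T3, 748645 for the library labelled ATRβKO (T3) and 757606 for floxed HFD, against 1891065 for the library labelled ATRβKO (HFD).

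Thrb (ENSMUSG00000021779), the targeted gene, was at 4.44 FPKM in floxed vehicle, 4.43 in floxed T3 and 4.26 in the library labelled ATRβKO (T3). A gene-level value does not separate a shortened transcript or the receptor of other cell types, so it does not check that label. On HFD, Thrb was at 4.38 FPKM in floxed mice and 170 FPKM in the library labelled ATRβKO (HFD), which the label does not account for. By the size rule 8447 of 17711 genes were higher in that library, so this value does not check its label either. Genes with long introns were among those higher (below), and whether reads in introns raised Thrb was not tested. Both libraries labelled ATRβKO are therefore named by their labels throughout. Thra (ENSMUSG00000058756), the related receptor gene, was at 50.4, 32.7 and 41.6 FPKM in the vehicle, floxed T3 and labelled ATRβKO (T3) libraries, and at 88.5 and 115 FPKM in the floxed and labelled ATRβKO HFD libraries.

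The first comparison asked what T3 did to iWAT of floxed mice. Ucp1, which uncouples mitochondrial respiration for heat, was 11.4-fold higher with T3 (278 against 24.3 FPKM), and genes of fatty acid synthesis were higher together. Of 16 de novo lipogenesis genes, 10 were higher by the size rule and none lower, with a median log2 ratio of 1.39. Acly, which makes cytosolic acetyl-CoA, went from 350 to 1389 FPKM, Fasn, the fatty acid synthase, from 1901 to 5127, Acaca from 189 to 537, Elovl6 from 46.5 to 183 and Acss2 from 92.1 to 371. Me1, the malic enzyme, stood at 349 and 1468 FPKM and Thrsp, a classic thyroid hormone target in fat, at 963 and 2367. Skeletal muscle markers lay on the other side, with 19 of 25 lower and a median log2 ratio of -1.76.

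Other metabolic lists stood apart in the same direction as lipogenesis. Pyruvate oxidation and TCA cycle genes had a median log2 ratio of 0.61 with 9 of 29 higher, among them the pyruvate carrier subunit Mpc1 (364 to 1084 FPKM) and the pyruvate dehydrogenase subunits Pdhb (252 to 738) and Dlat (73.1 to 213). Glucose uptake and glycolysis genes had a median of 0.69 with 3 of 20 higher (Eno1, Pfkl and Pgk1), and the insulin-responsive glucose transporter Slc2a4 was at 169 against 99.6 FPKM, short of 2-fold. Glycogen genes had a median of 0.05 with 4 of 16 higher and 1 lower, including Gys2 (7.30 to 30.2 FPKM) and Pygl (109 to 305). Thermogenic genes had a median of 0.60 with 7 of 19 higher and 2 lower, including Cox7a1 (55.2 to 259 FPKM), Acot11 (3.64 to 17.6) and Otop1 (6.08 to 22.1). Lists can share members. The lower glycogen gene, Pygm, and the 2 lower thermogenic genes, Atp2a1 and Ckmt2, are also in the skeletal muscle list. These genes were picked out after their values were seen. Cholesterol synthesis stood at 0.74 with 4 of 21 higher, led by Fdps (30.7 to 98.2 FPKM), fatty acid oxidation at 0.39 with 3 of 21, and triglyceride synthesis and fatty acid uptake at 0.39 with 3 of 19. Nuclear-encoded oxidative phosphorylation had a median of 0.57 with all 34 members above 0 and none 2-fold higher. Thyroid hormone response genes (0.15, 5 of 16 higher), mitochondrially encoded transcripts (0.41, 1 of 15), lipolysis and lipid droplet genes (0.16, 1 of 18 higher and 1 lower), interferon response (0.14, 1 of 20), proliferation (0.08, 0 of 25) and endothelial markers (0.24, 0 of 20) also stood apart upward.

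Some lists of other cell types stood apart downward in the same library, and endothelial markers, above, stood apart upward. The muscle genes Ckm (319 to 58.8 FPKM), Tnnt3 (517 to 109) and Pvalb (193 to 37.8) were about 5-fold lower. T and NK cell markers had a median log2 ratio of -0.97 with 11 of 23 lower, including Lck (40.7 to 15.9 FPKM) and Cd3g (44.7 to 17.2), and B and plasma cell markers -0.71 with 0 of 17. Macrophage (-0.38, 1 of 22 lower), preadipocyte and fibroblast (-0.46, 2 of 20), ribosomal protein (-0.45, 0 of 30), circadian clock (-0.53, 5 of 17) and immediate early genes (-0.44, 0 of 20) stood apart downward. Adipocyte identity genes did not stand apart by their median (-0.14) but did by their mean (-0.44), and Nnat was 8.45-fold lower (829 to 98.1 FPKM) and Adipoq, which encodes adiponectin, was at 781 against 1498 FPKM. Lep was at 140 against 232 FPKM and Pck1 at 369 against 628. Mlxipl was at 111 against 76.2 FPKM. All 3 were short of 2-fold. Lists that did not stand apart were hormone receptors and handling (-0.30), pentose phosphate and hexosamine pathways (0.04), insulin signalling (-0.17), futile cycles (-0.10), stress response (-0.34), cytokines (-0.28), extracellular matrix (-0.26), neutrophil and mast cells (-0.31), mural cells (-0.24), mammary epithelium (-0.30), Schwann cells (-0.41) and erythroid markers (0.42).

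**Figure D1:**
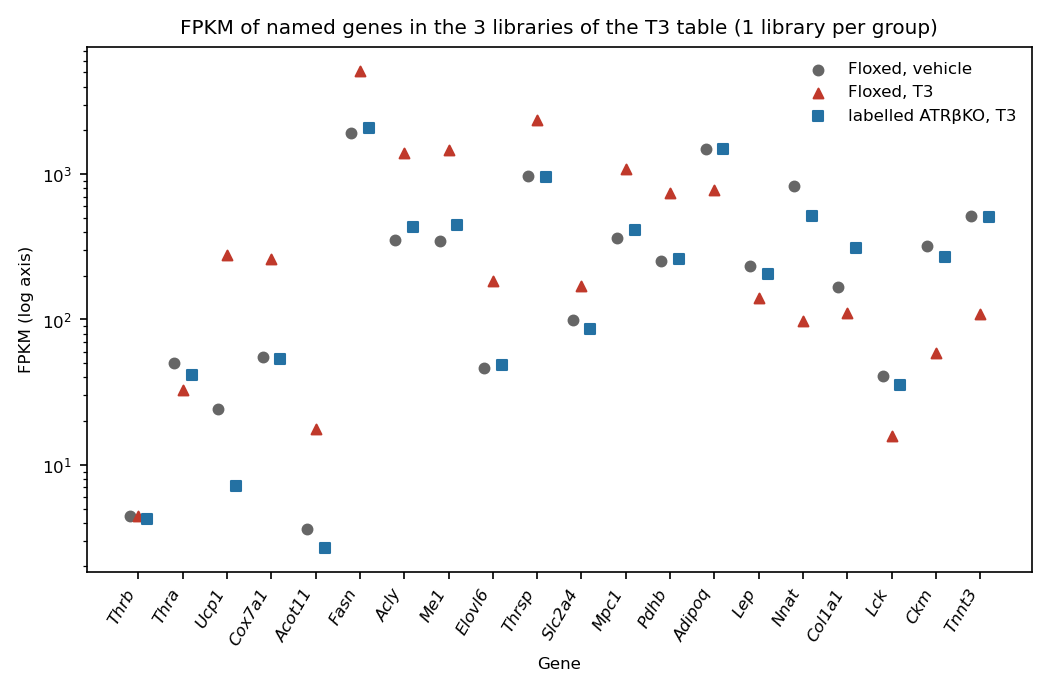
FPKM on a log axis of 20 genes in the 3 libraries of the first table, 1 point per library, with no error bars because there is 1 library per group. Ucp1 is at 24.3, 278 and 7.13 FPKM in floxed vehicle, floxed T3 and the library labelled ATRβKO (T3), and for Fasn, Acly, Me1, Ckm and Tnnt3 the floxed T3 point lies away from the other two.

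Of 15031 genes compared, 346 were higher and 598 lower with T3, and the median log2 ratio of all of them was -0.21. The split was 468 and 445 after rescaling to a median of 0, 502 and 422 after TMM rescaling, 393 and 476 without the 50 most abundant genes, and 313 and 679 at a common total, an alternative chosen after seeing the data. The excess of lower genes thus depends on the scaling. The largest and smallest log2 ratios were mostly of small nucleolar RNAs and clone-named genes listed at 0 in one library, such as Snord94 (0 and 40.4 FPKM in vehicle and T3) and Snord15a (53.4 and 0), whose short transcripts FPKM measures poorly. The lipolysis and mitochondrially encoded lists did not stand apart under at least 1 of the 10 alternatives. Of lists that did not stand apart, Schwann cell and erythroid markers did so under 4 each, pentose phosphate and hexosamine pathways under 2, and neutrophil and mast cell markers under 1.

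The second comparison asked how iWAT of mice labelled ATRβKO differed from floxed iWAT when both were given T3. Of the 346 genes higher with T3 in floxed mice, 185 (53.5%) were at least 2-fold lower in the library labelled ATRβKO (T3) than in floxed T3. Of the 598 lower genes, 236 (39.5%) were at least 2-fold higher. Both comparisons share floxed T3, so some return is built in. Simulated unchanged libraries gave 49.2% and 29.6%, with scatter taken from the library labelled ATRβKO (T3) against vehicle. In them every call came from scatter, so they do not tell how much of the return seen here comes from the shared library. Ucp1 was 39.0-fold lower (7.13 against 278 FPKM), and 11 of 19 thermogenic genes were lower and 2 higher, with a median log2 ratio of -1.41. The 2 higher ones, Atp2a1 and Ckmt2, are also muscle markers. De novo lipogenesis genes had a median of -1.31 with 10 of 16 lower, including Fasn at 2068 against 5127 FPKM, Acly at 429 against 1389, Acaca at 230 against 537, Elovl6 at 48.3 against 183 and Thrsp at 954 against 2367. Muscle markers were higher, 20 of 23, with a median of 2.12 (Pvalb 205 against 37.8 FPKM, Myh4 233 against 45.8).

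Pyruvate oxidation and TCA cycle genes had a median log2 ratio of -0.72 with 7 of 29 lower, including Mpc1 (415 against 1084 FPKM) and Pdhb (259 against 738). Glucose uptake and glycolysis genes stood at -0.71 with 1 of 20 lower and 1 higher, with Slc2a4 at 86.3 against 169 FPKM and Hk2 at 25.8 against 52.4. Glycogen genes were at -0.26 with 4 of 16 lower and 2 higher, including Ppp1r3b (7.13 against 39.1 FPKM) and Pygl (113 against 305). The muscle marker Pygm was among the higher ones. Fatty acid oxidation (-0.62, 5 of 21 lower), oxidative phosphorylation (-0.60, 0 of 34), mitochondrially encoded transcripts (-0.62, 1 of 15), cholesterol synthesis (-0.68, 4 of 21), triglyceride synthesis (-0.33, 1 of 19), lipolysis (-0.15, 2 of 18), thyroid hormone response (-0.27, 6 of 16) and endothelial markers (-0.25, 0 of 20) also stood apart downward. Me1 was at 445 against 1468 FPKM, Cidea at 35.6 against 162 and Plin2 at 245 against 502.

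Extracellular matrix genes had a median log2 ratio of 0.71 with 5 of 26 higher, including Col1a1 (311 against 111 FPKM), Col3a1 (1031 against 454) and Fn1 (225 against 101). Macrophage markers stood at 0.68 with 2 of 22 higher, Trem2 (29.7 against 9.19 FPKM) and Gpnmb (25.2 against 9.75). Neutrophil and mast cell markers (0.57, 3 of 12 higher), preadipocyte and fibroblast (0.67, 2 of 20), T and NK cell (0.63, 2 of 23), B and plasma cell (0.53, 0 of 17), Schwann cell (0.52, 0 of 11 higher and 1 lower), mural cell (0.41, 0 of 15), stress response (0.38, 0 of 16), immediate early (0.39, 0 of 20) and ribosomal protein genes (0.33, 1 of 30) stood apart upward. Adipoq (1482 against 781 FPKM), Pck1 (732 against 369), Lep (206 against 140) and Mlxipl (60.7 against 111) were short of 2-fold, and adipocyte identity genes did not stand apart by their median (0.19) but did by their mean (0.36). Interferon response (0.17), hormone receptors (0.32), pentose phosphate and hexosamine pathways (-0.04), insulin signalling (0.14), futile cycles (0.16), cytokines (0.16), proliferation (0.03), circadian clock (0.11), mammary epithelium (0.15) and erythroid markers (0.20) did not stand apart. Eno1b, a retrocopy that can share reads with Eno1, was at 0.59 against 465 FPKM and is uncertain for that reason.

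Of 14988 genes, 606 were higher and 302 lower, with a median log2 ratio of 0.18. The split was 431 and 400 after rescaling to a median of 0, 408 and 421 after TMM rescaling, 478 and 389 without the 50 most abundant genes, and 701 and 276 at a common total. Schwann cell, ribosomal protein, immediate early, lipolysis, mitochondrially encoded, mural, neutrophil and mast cell, and stress response lists did not stand apart under at least 1 alternative. Proliferation genes, inside the random range above, stood apart under 2, and circadian clock and pentose phosphate and hexosamine pathways under 1 each.

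Of the 346 genes higher with T3 in floxed mice, 75 were also at least 2-fold higher than vehicle in the library labelled ATRβKO (T3), and the median share of the log2 difference kept was 0.17. It ran from 0.067 at 4-fold to 0.241 with a pseudocount of 0.1, and was 0.088 with a pseudocount of 5. Of the 598 lower genes, 174 were also lower, with a median share of 0.34, which ran from 0.234 with a floor of 5 to 0.554 at 4-fold. Exchangeable libraries would give 0.5 only where scatter is alike in both directions. With the roles exchanged, the share ranged from 0.005 to 0.66 for higher genes and from 0.373 to 0.995 for lower genes. Neither share can therefore be read as low against 0.5. Over 8578 genes at 5 FPKM or more in 4 libraries, the SD of log2 ratios was 0.23 between the library labelled ATRβKO (T3) and vehicle, 0.38 between floxed T3 and vehicle and 0.39 between both T3 libraries. Floxed T3 stood 2-fold apart from both others in 274 genes, vehicle in 107 and the library labelled ATRβKO (T3) in 99. Across 15439 genes, which are not independent replicates, the T3 and genotype log2 ratios had r = -0.63 with a covariance of -0.19, against -0.50 and -0.11 in simulated unchanged libraries that share floxed T3 in the same way. The simulated scatter was that of the library labelled ATRβKO (T3) against vehicle, the closest pair, so weaker simulated values were built in. The excess restates the SDs above and does not show a return beyond the shared library.

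**Figure D2:**
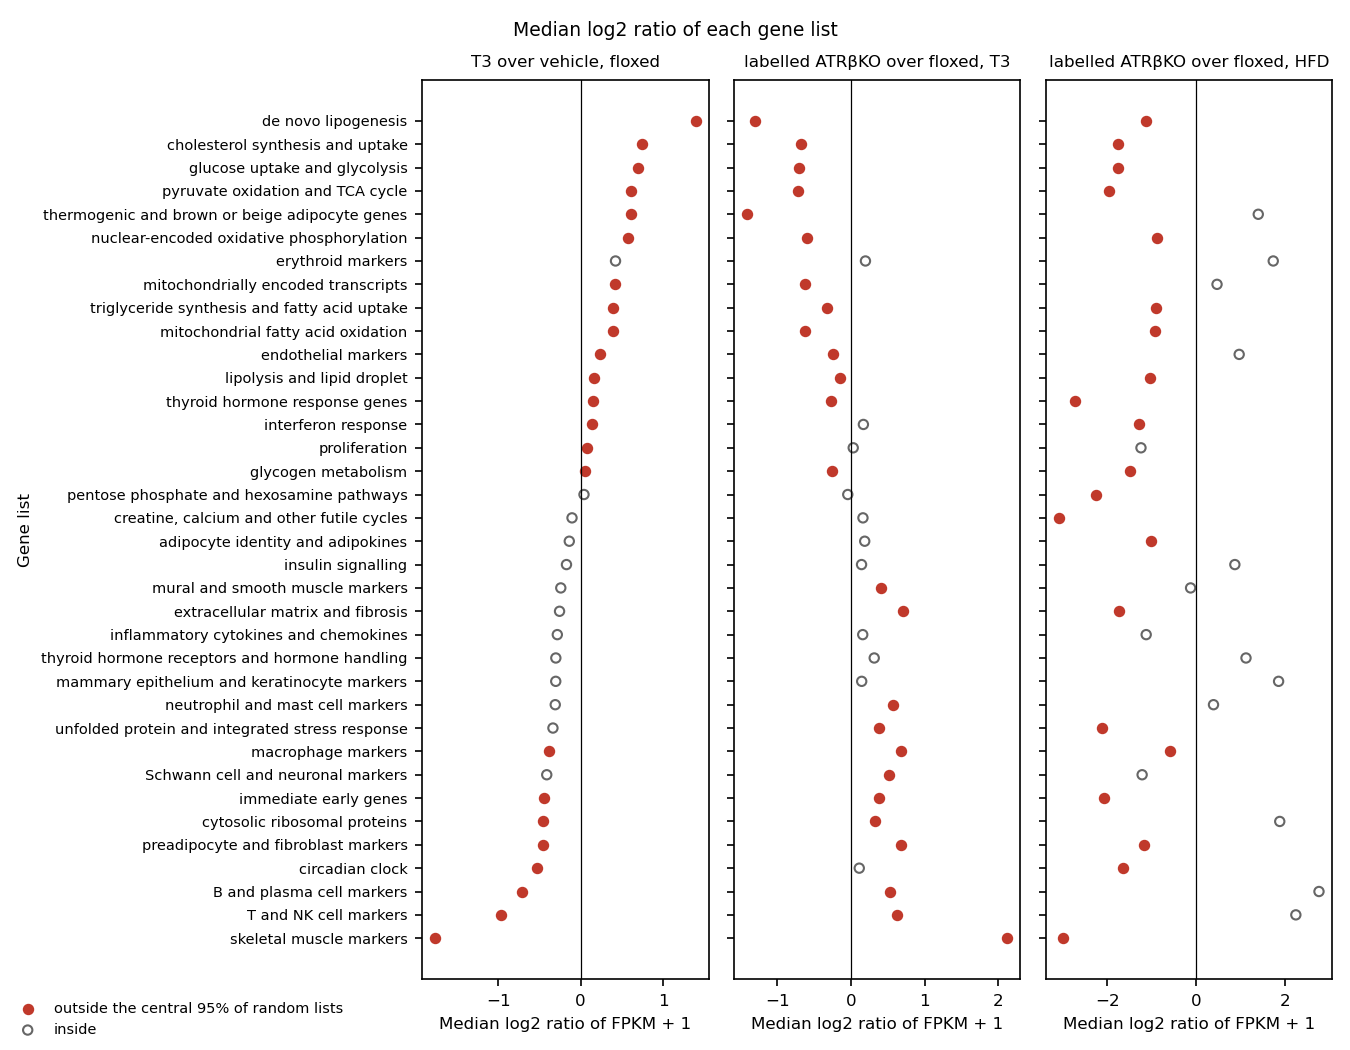
Median log2 ratio (FPKM plus 1) of the 36 evaluated gene lists in the 3 comparisons, 1 point per list, with filled points outside the central 95% of matched random lists. De novo lipogenesis is at 1.39 for T3 over vehicle and at -1.31 for labelled ATRβKO over floxed on T3, and skeletal muscle markers are at -1.76 and 2.12.

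The third comparison asked how genotype related to expression on HFD. The library labelled ATRβKO (HFD) differed from floxed HFD in most genes, in both directions. No list stood apart upward and 21 of 36 stood apart downward from random lists, but this depends on how the random lists are matched. Alternatives added after seeing the data took floxed HFD alone in place of both libraries. Matching by it left 7 of 36 lists downward and 2 upward, and choosing genes by it left 17 of 35 downward and 1 upward. With both, 6 of 35 stood apart downward, 5 of them among the 21, and 2 upward. The 6 were thyroid hormone response, futile cycle, stress response, proliferation, immediate early and skeletal muscle genes, and the 2 were ribosomal protein and endothelial genes. The other lists, among them adipocyte identity, glycolysis, pyruvate oxidation and lipogenesis, then lay inside the random range, as the random medians moved and the medians of these 4 did not. Adipocyte identity genes had a median log2 ratio of -1.01 with 10 of 19 lower and 5 higher, including Adipoq (140 against 2632 FPKM) and Cebpa (5.49 against 232). Glucose uptake and glycolysis genes stood at -1.75 with 15 of 20 lower and 2 higher, including Ldha (17.6 against 829 FPKM), and Slc2a4 was listed at 0 against 79.4. Pyruvate oxidation and TCA cycle genes were at -1.95 with 22 of 29 lower, including Mpc1 (1.34 against 332 FPKM) and Pdha1 (1.24 against 112).

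De novo lipogenesis genes had a median log2 ratio of -1.12 with 8 of 16 lower and 4 higher, with Scd1 at 93.4 against 4449 FPKM, Fasn at 279 against 732, Acaca at 17.0 against 21.7 and Acly at 33.4 against 61.0. Thyroid hormone response genes stood at -2.73 with 11 of 19 lower and 5 higher (Pck1 6.78 against 337 FPKM, Thrsp 45.0 against 315), skeletal muscle markers at -2.99 with 19 of 24 lower and extracellular matrix genes at -1.73 with 16 of 26 lower (Fn1 4.77 against 146 FPKM). Thermogenic genes did not stand apart (1.39, 11 of 20 higher and 6 lower), and Ucp1 was at 9.74 against 2.04 FPKM. Lep was at 166 against 1723 FPKM and Mlxipl at 5.30 against 44.8. The other lists that stood apart downward were futile cycles (-3.09), pentose phosphate and hexosamine pathways (-2.24), stress response (-2.12), immediate early genes (-2.07), cholesterol synthesis (-1.76), circadian clock (-1.65), glycogen (-1.48), interferon response (-1.29), preadipocyte and fibroblast markers (-1.18), lipolysis (-1.04), fatty acid oxidation (-0.92), triglyceride synthesis (-0.90), oxidative phosphorylation (-0.87) and macrophage markers (-0.58). Those that did not were hormone receptors (1.11), mitochondrially encoded transcripts (0.46), insulin signalling (0.86), cytokines (-1.12), proliferation (-1.24), ribosomal proteins (1.87), B cells (2.75), T and NK cells (2.23), neutrophil and mast cells (0.39), endothelial (0.96), mural (-0.13), mammary (1.85), Schwann (-1.22) and erythroid markers (1.73), set against random lists whose medians ran from -0.01 for proliferation to 1.11.

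Genes with the largest log2 ratios were Dcdc2c (595 against 0.22 FPKM), Tnxa (23765 against 65.5), Prkg1 (549 against 1.07), Lrp1b (249 against 0) and a pair of 5S ribosomal RNA genes. At the other end, the mitochondrial transcripts mt-Co1 and mt-Cytb, at 12982 and 6303 FPKM in floxed HFD, were listed at 0, while mt-Nd6, chosen after its values were seen, was at 145282 against 2277 FPKM. Of 17711 genes, 8447 were higher and 5660 lower, with a median log2 ratio of 0.80. The split was 7018 and 6667 after rescaling to a median of 0, 6787 and 7446 without the 50 most abundant genes, and 6260 and 8286 at a common total. The values of single genes also depend on the scaling. Of the 98 genes the rule took, 95 moved by over 1.5-fold at a common total and 79 without the 50 most abundant genes. Adipocyte identity, de novo lipogenesis, circadian clock, lipolysis, fatty acid oxidation, triglyceride synthesis and macrophage lists did not stand apart under at least 1 of the 10 other alternatives. Proliferation stood apart under 5, cytokines and T and NK cells under 2 each, and B cell, mitochondrially encoded and mural lists under 1 each. Over the 8578 genes, the SD of log2 ratios was 2.39 between the HFD libraries, against 0.69 between floxed HFD and floxed vehicle, and 73.0% of the genes were at least 2-fold apart. Every direction given here rests on a label that the Thrb value does not bear out, in a library that lists mt-Co1 at 0.

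**Figure D3:**
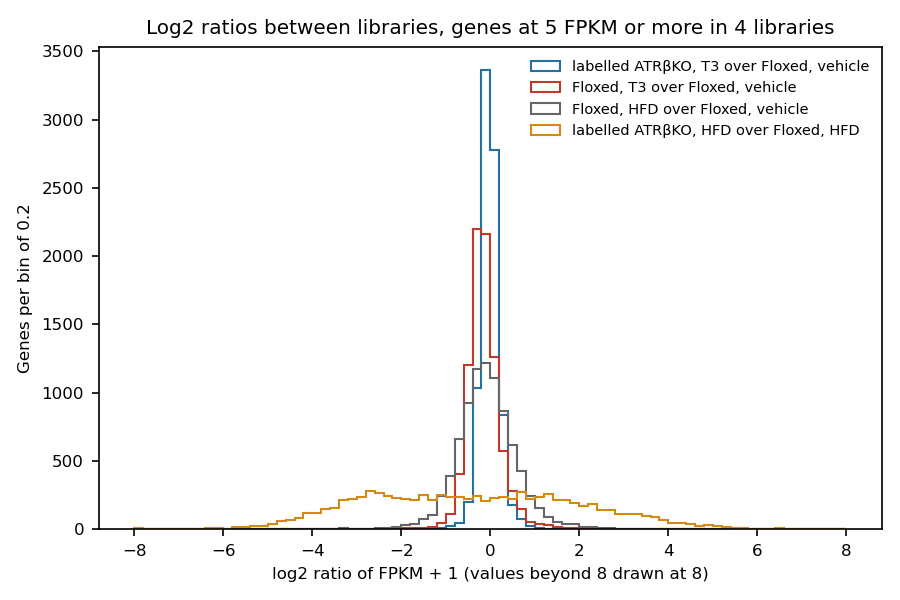
Distribution of log2 ratios (FPKM plus 1) for 4 pairs of libraries over 8578 genes, drawn as genes per bin. The SD is 0.23 for the library labelled ATRβKO (T3) over vehicle, 0.38 for floxed T3 over vehicle, 0.69 for floxed HFD over vehicle and 2.39 for the library labelled ATRβKO (HFD) over floxed HFD.

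The genotype differences on T3 and on HFD had r = -0.002 and rho = 0.015 across 13634 genes, which are not independent replicates. Of these, 121 were higher in both where independent lists would share 153, and 92 were lower in both against 80.0. These counts depend on the scaling: they were 64 and 160 at a median of 0, 59 and 169 with TMM, and 66 and 154 without the 50 most abundant genes. At the deposited scaling, a further 211 were higher on T3 and lower on HFD, against 169, and 70 were lower on T3 and higher on HFD, against 72.7.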

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

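All tests on the T3 libraries and on tissue makeup were chosen after the results were seen, as were those on depth, silent genes, receptor loss and genes with the least intron sequence. Those on strand, the trend with intron length and neighbouring genes were fixed before.

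Lists stood apart upward in the library labelled ATRβKO (T3) and downward in the library labelled ATRβKO (HFD), each against its floxed library, though with random lists matched by floxed HFD alone only stress response, immediate early and muscle genes still did so on HFD. The difference was not tested, as there is 1 library per group. The HFD minus T3 difference of the median log2 ratio was -2.50 for the unfolded protein and integrated stress response, -2.44 for extracellular matrix, -2.46 for immediate early genes, -1.26 for macrophage markers, -1.86 for preadipocyte and fibroblast markers and -5.12 for skeletal muscle markers.

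The library labelled ATRβKO (HFD) differs from the 4 others across most expressed genes. Assignment of its reads as a whole to the wrong strand is argued against. Its values followed the genes themselves and not their opposite-strand partners (rho difference -0.918 over 5390 genes). The test cannot speak to wrong assignment of a part of the reads. Shallow sequencing (estimated depth 0.635 of floxed HFD) and shifts to neighbouring genes (odds ratio 1.13) are also argued against. Reads from genomic DNA or unspliced RNA may contribute: of protein-coding genes under 0.1 FPKM in the 4 others, 560 of the 1406 with the longest introns were at 1 FPKM or more against 14 of the 1407 with the shortest, a ratio of 40.0, and log2 ratios of expressed genes rose with intron length (rho 0.296, just short of the bound set before, against -0.128 for floxed HFD over vehicle), but they are not the whole cause, since the SD was 2.44 in the 833 expressed genes with the least intron sequence. Receptor loss as a part of the cause stays open. Of 64 oxidative phosphorylation and ribosomal protein genes at 10 FPKM or more in floxed HFD, 0.0% were listed at 0, which met the bound set for it. Outside that test, 3 of 15 mitochondrially encoded transcripts were listed at 0. Genes listed at 0 cannot tell receptor loss from other causes, so this gives it no support. As the whole cause, receptor loss would keep subunits in proportion, while the log2 ratios of the 64 had an SD of 2.47. What else scattered these values was not found.

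The library labelled ATRβKO (T3) lies closer to vehicle than to floxed T3. That is what loss of the receptor would give, and also what a library from vehicle-treated floxed mice would give. The latter stays open: vehicle stood apart from both T3 libraries in 107 genes and the labelled library from both floxed ones in 99, a ratio of 1.08, which that explanation asks for. Against it, and against T3 failing to reach these mice, which cannot be told apart, 11 major urinary protein (Mup) genes 2-fold higher in floxed T3 had a median log2 ratio over vehicle of 1.87 in this library (1.58 to 2.86), but they share reads as 1 family, both ratios use the same vehicle library, and no spread between libraries is known. Thrb gives no check of the label.

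Skeletal muscle and lymphocyte markers are lower in floxed T3 than in both other libraries of its table. Less muscle in the pooled tissue is a candidate explanation, since 13 muscle markers at 50 FPKM or more in vehicle were lower by nearly the same amount (SD 0.233 of log2 ratios, from -2.42 for Ckm to -1.73 for Eno3). An effect of T3 on muscle fibres of the depot was not tested. A lower share of other tissue would raise all adipocyte RNA alike. It is argued against as the cause of the higher de novo lipogenesis genes, since adipocyte identity genes lay 1.53 log2 units below them (difference -1.53). For the other metabolic lists this was not tested. Medians such as 0.39 for fatty acid oxidation and 0.69 for glycolysis lay nearer to that of adipocyte identity (-0.14) than the lipogenesis median did. Adipocyte identity genes were themselves not raised, with 15 of 19 below 0 and 4 above, which a rise of all adipocyte RNA alike would not give by itself. Nearness to them therefore gives this explanation no support, and no conclusion is drawn for these lists.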

How the results depend on the processing

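Rescaling to a common total, leaving out muscle and lymphocyte list members, leaving out genes listed at 0, centring by intron length and choosing or matching HFD lists by floxed HFD alone were chosen after seeing the data. No paired analysis was possible because each group has 1 library and no test was run. No other deposited unit is in the tables, so that alternative was not run, and leaving out a library was not possible. Over the count of genes, list counts, shares and correlations, 140 values stayed within the tolerance and 65 did not, mostly with the size rule, pseudocount and floor, which by construction change how many genes can pass. The tolerance is 1.5 times the reported count, so a count within it can still differ much (502 T3-higher genes with TMM against 346), and for shares and r the 95% bootstrap interval over genes. T3 over vehicle gave, higher and lower, 785 and 2108 genes at 1.5-fold, 68 and 86 at 4-fold, 136 and 140 with a pseudocount of 5, 202 and 309 with a floor of 5, and 1088 lower with a pseudocount of 0.1. The genotype comparison on T3 gave 2008 and 758, 94 and 54, 192 and 116, 355 and 167, and 1093 and 474 in the same order. On HFD the lower genes numbered 3565 with a pseudocount of 5 and 3179 at 4-fold. Genes also higher and also lower in the library labelled ATRβKO (T3) numbered 137 and 307 with a pseudocount of 0.1, 20 and 32 with 5, 40 and 60 with a floor of 5, 176 and 406 at 1.5-fold and 18 and 36 at 4-fold. The share kept by lower genes was 0.287 and 0.246 with these pseudocounts, 0.234 with the floor, 0.428 at a median of 0, 0.448 with TMM, 0.438 without the 50 most abundant genes, 0.263 at 1.5-fold and 0.554 at 4-fold. That of higher genes was 0.088 with a pseudocount of 5, 0.067 at 4-fold and, within the tolerance, 0.241 with a pseudocount of 0.1. Genes higher in both genotype comparisons numbered 294 with a pseudocount of 0.1, and higher and lower 28 and 42 with 5, 60 and 60 with the floor, 64 and 160 at a median of 0, 59 and 169 with TMM, 66 and 154 without the 50 most abundant genes, 680 and 288 at 1.5-fold and 7 and 9 at 4-fold. Without genes listed at 0, 54 were lower in both, and r was -0.025 with no floor. Lists higher on HFD numbered 1 with a pseudocount of 5 and 2 with no floor, against 0 as reported. By floxed HFD alone, lists higher and lower numbered 2 and 6 when chosen and matched, 1 and 17 when only chosen and 2 and 7 when only matched, against 0 and 21. For the scaling rows the cause was not tested. No list was reversed. In all, 21 of 23, 17 of 25 and 14 of 21 lists that stood apart did so under all 10 other alternatives in the T3, genotype on T3 and HFD comparisons. Without muscle and lymphocyte list members, T3 over vehicle gave 346 and 568 genes.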

Other observations

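The tests here were chosen after the data were seen. Against vehicle, the library labelled ATRβKO (T3) had 277 genes higher and 272 lower of 15175. Thermogenic genes stood apart below vehicle (median log2 ratio -0.48, 3 of 19 lower), with Ucp1 at 7.13 against 24.3 FPKM and Cidea at 35.6 against 106. In all, 9 lists stood apart downward and 8 upward. The others downward were T and NK cell markers (-0.34), circadian clock (-0.30), mitochondrially encoded transcripts (-0.23), fatty acid oxidation (-0.19), B and plasma cell markers (-0.18), adipocyte identity (-0.17), pyruvate oxidation and TCA cycle (-0.11) and ribosomal protein genes (-0.09). Those upward were erythroid markers (0.60, 5 members), extracellular matrix (0.42), interferon response (0.29), macrophage (0.28), neutrophil and mast cell (0.24), preadipocyte and fibroblast markers (0.18), pentose phosphate and hexosamine pathways (0.12) and triglyceride synthesis (0.11). De novo lipogenesis genes did not stand apart (0.09).

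The Mup genes, which encode secreted carriers of small lipophilic molecules, were higher than vehicle in both T3 libraries for 14 of 15 measured members. Mup18 was at 3170, 8327 and 11579 FPKM in vehicle, floxed T3 and the library labelled ATRβKO (T3), and Mup10 at 230, 524 and 761. These genes were chosen after their values were seen, and as near-identical copies they share reads. Serpina3k, also chosen afterwards, was at 1.72 and 1.24 FPKM in the floxed vehicle and T3 libraries and at 25.9 FPKM in the library labelled ATRβKO (T3).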
